A study of Mus musculus with 96 samples.

How the data were processed

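RNA was sequenced from epidermis separated with dispase from the back skin of male C57BL/6 mice aged 8 weeks, kept in 12 h of light and 12 h of dark. Poly(A) RNA went into stranded libraries, and 4 mice per genotype were sampled at each of 6 times, 4 h apart, starting at lights on (zeitgeber time 0, ZT0). Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to mouse genome mm10 with HISAT2 2.2.1 and SAMtools 1.3.1, counted per gene with featureCounts 1.6.0 and normalized with edgeR, whose version is not given.

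The deposited tables, 1 per genotype, give 1 log2 value per gene and library. No label names the unit. The values behave as log2 RPKM (reads per kilobase of transcript, scaled to library depth) to which the authors added a prior count, inferred here as 2 reads, and this unit is used throughout. The authors also deposited, per gene and genotype, the q value of a JTK_CYCLE run and of a BIOCYCLE run, both of which search for daily rhythms. The third deposited quantity is the peak time in hours of each of those runs, which is not used here. The 96 sample columns of the deposited JTK_CYCLE tables repeat the same expression values and were not used a second time.

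Whole read counts could be recovered, within 0.05 reads, only for weakly expressed genes (7255 in WT, 7421 in RERE, 7478 in EpiRE and 7474 in BRE). The log2 values were therefore tested as they are, with no added pseudocount and no count-based test. Depth per library was estimated from the floor that the prior count leaves. The floors show that each genotype's table was normalized apart from the others (offsets against WT of 0.031 log2 in RERE, 0.132 in EpiRE and 0.106 in BRE). Mean levels are for that reason set side by side but were not tested between genotypes. The rhythm tests carry a free mean per genotype, so a constant offset between tables drops out of them.

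Of 22384 genes in all 4 tables, the 12144 with a mean of at least 1 RPKM over all libraries were tested and 10240 were not. Rhythms were tested within each genotype with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), as an F test, open to either direction, of the cosine and sine terms of a 24 h harmonic with 2 degrees of freedom. P-values were adjusted over all tested genes by Benjamini and Hochberg, and a gene was called at an adjusted p below 0.05. Rhythm differences between 2 genotypes were tested on their 48 libraries with the F test of the terms genotype by cosine and genotype by sine. The size of a rhythm is the fitted peak-to-trough difference on the log2 scale, given with its standard error, and peak times are fitted zeitgeber times. Each rhythm rests on 24 libraries, 4 mice at each time.

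Genes were also sorted among 52 models of shared, different or absent rhythms in the 4 genotypes by the Bayesian information criterion (BIC), and assigned where the best model held a weight of at least 0.4. Overlaps of called genes were tested with two-sided Fisher's exact tests, which treat genes as independent. Peak shifts and amplitude ratios are medians over genes called in both genotypes, with jackknife errors over the 4 replicate numbers.

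The design, the tests, 26 gene lists and the rule for naming genes were fixed before the data were examined. The lists hold core clock genes, DNA replication and S phase, G2 and mitosis, basal keratinocytes, keratinocyte differentiation, hair follicle and sebaceous gland, heat shock response, cold-inducible RNA-binding proteins, glucocorticoid response, fasting and lipid oxidation, glycolysis, nuclear-encoded oxidative phosphorylation, cholesterol and fatty acid synthesis, antioxidant targets of Nrf2, DNA excision repair, immediate early and dissociation response, and clock output genes shared across tissues. The other lists hold markers of T cells, Langerhans and dendritic cells, melanocytes, fibroblasts, endothelium, skeletal muscle, adipocytes, blood, and hair shaft and matrix. Each list was tested for called members against the other tested genes with Fisher's exact test, adjusted over the lists of a comparison, and members were also counted when adjusted over the list alone. The mean of each list per library was fitted with the same harmonic and tested by permuting time labels (100000 resamples, adjusted over 96 fits). That test was added after the data were examined.

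Genes are named by rule: every core clock gene, the 12 largest rhythms per genotype among called genes with a mean of at least 10 RPKM, the 12 smallest adjusted p-values per rhythm difference, up to 4 members per list plus any member needed to state a list's result, and the 6 highest BIC weights in each of 4 model classes. Predicted genes were counted but passed over, and some genes named by the rule, and a test that rests on 1 of them, are not reported here. Positions were taken from the GENCODE M21 annotation of mm10, which held 22317 of the genes.

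The tests were checked on simulated data, with Gaussian noise drawn apart for each gene around its real mean, at its real residual SD. In these data 200 genes were given rhythms. Real genes vary together and many more of them were called, so the shares below need not carry over. A 2-fold rhythm was recovered for 87.9 to 93.9% of such genes within a genotype, and a 2-fold rhythm present in only 1 of a pair of genotypes for 78.8 to 87.9%. At 1.5-fold the shares were 70.1 to 73.1% and 55.2 to 67.2%. False calls made up 0.909 to 7.19% of calls. Among unchanged genes, 519 (4.35%) were given a rhythmic model by the BIC.

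Alternatives were a mean of at least 5 RPKM, no filter on low values (20113 genes), pseudocounts of 0.1 and 1, median-of-ratios rescaling of each genotype's libraries, limma array weights, 1 fit on all 96 libraries, replicate number as a block, time as a 6-level factor, a peak-to-trough of at least 1.5-fold, the authors' q values, a BIC weight of 0.6, an adjusted p below 0.01 for overlaps, and leaving out replicate numbers and single libraries. Figures and permutation checks used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.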

Results

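Messenger RNA was measured in 96 libraries of mouse back-skin epidermis, 24 from each of 4 genotypes, with 4 mice at each of ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20. WT mice have an intact clock. In the 3 other genotypes Arntl, which encodes the clock activator BMAL1, carries a stop cassette that Cre removes. Removal takes place in brain and epidermis in RERE (Syt10-Cre and K14-Cre), in epidermis alone in EpiRE (K14-Cre) and in brain alone in BRE (Syt10-Cre). Estimated depth ranged from 11.2 M to 32.4 M reads (M for mega) per library, with a median of 16.5 M. The median was 17.8 M in WT, 16.5 M in RERE and 14.7 M in EpiRE, and BRE libraries held 12.0 M to 19.1 M. Reads counted per gene do not show whether an Arntl transcript is functional, so the Arntl level does not check the genotype labels. All rhythm sizes below are fitted peak-to-trough log2 differences ± SE over 24 mice per genotype.

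The rhythms of WT epidermis set the reference. Core clock genes had large ones. Per2, a clock repressor (ENSMUSG00000055866, mm10 chromosome 1, 91415982 to 91459324, minus strand), varied by 6.14 ± 0.34 log2, or 70.7-fold, with its peak at ZT13.1 (adjusted p = 1.99e-10). Dbp, a clock-driven transcription factor (chromosome 7, 45705088 to 45710203, plus strand), varied by 5.49 ± 0.34 log2 with its peak at ZT10.2 (adjusted p = 8.36e-10). Nr1d1, which encodes the repressor REV-ERB alpha (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333, minus strand), varied by 4.03 ± 0.14 log2 with its peak at ZT7.47 (adjusted p = 1.75e-14). Its mean was 143 RPKM at ZT8 and 8.59 RPKM at ZT20 (n = 4 mice each). Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, plus strand) peaked at ZT22.6 with 2.31 ± 0.15 log2 (adjusted p = 1.5e-09), close to Npas2, a partner of BMAL1, at ZT23.2 (2.78 ± 0.18 log2). Cry1, a repressor that acts late in the cycle, peaked at ZT17 (2.62 ± 0.18 log2). Of 18 core clock genes tested, 16 were called and 17 when adjusted over the list alone. Nfil3 (adjusted p = 0.68) and Rora (adjusted p = 0.0763) were not called, and Bhlhe41 was too weakly expressed to test.

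**Figure D1:**
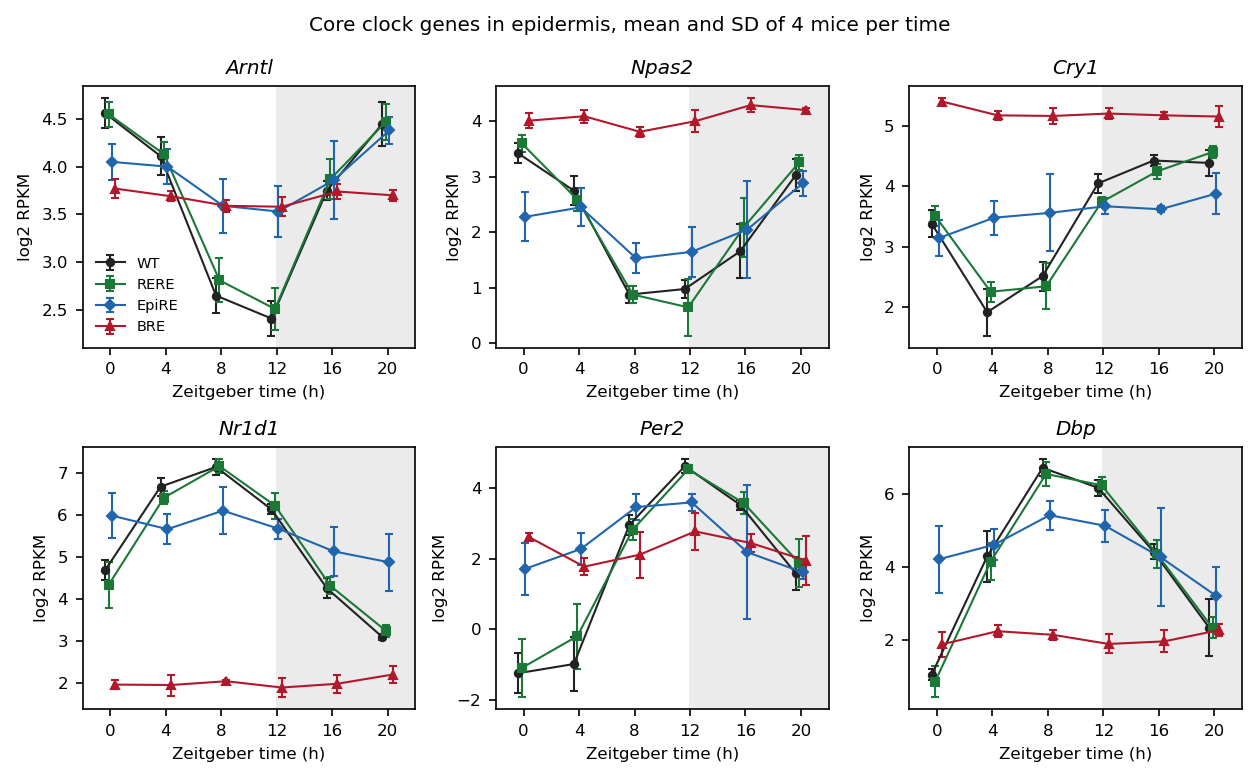
Level of Arntl, Npas2, Cry1, Nr1d1, Per2 and Dbp (log2 RPKM) against zeitgeber time (h), as mean ± SD of 4 mice in each of 4 genotypes, with the dark phase in grey. WT and RERE run together, EpiRE varies less (Per2 2.15 log2 from peak to trough, against 6.14 in WT), and BRE varies least, with Npas2 and Cry1 high and Nr1d1 and Dbp low.

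The cell cycle lists came next in WT. Of 29 tested genes of DNA replication and S phase, 27 were called (28 adjusted over the list alone; Fisher's exact test, adjusted p = 6.21e-10). They included Mcm2, a subunit of the replicative helicase (ENSMUSG00000002870, chromosome 6, 88883474 to 88898780, minus strand), with 1.33 ± 0.17 log2 and a peak at ZT14.1. Cdt1, which loads that helicase, varied by 1.33 ± 0.14 log2 with a peak at ZT13.6, and Pcna, the sliding clamp, by 0.58 ± 0.06 log2 with a peak at ZT15. All 28 genes of G2 and mitosis were called, also when adjusted over the list alone (adjusted p = 2.33e-12). Top2a, the mitotic DNA topoisomerase, varied by 1.72 ± 0.18 log2, Nusap1, a spindle protein, by 2.05 ± 0.18 log2 with a peak at ZT22.4, and Ube2c, which helps to end mitosis, by 1.40 ± 0.10 log2 with a peak at ZT23.3. The mean of the S phase list peaked at ZT14.8 (0.85 ± 0.09 log2, permutation test, adjusted p = 1.9e-04), and that of the mitosis list at ZT22.7 (1.37 ± 0.14 log2, adjusted p = 1.9e-04).

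Several other large rhythms in WT peaked in the late light phase. Fkbp5, a co-chaperone induced by glucocorticoids, varied 4.58-fold with a peak at ZT11.8 (adjusted p = 0.00118). Glul, the glutamine synthetase gene, peaked at ZT11.2 (1.81 ± 0.24 log2) and Slc6a6, a taurine transporter, at ZT10.3 (1.78 ± 0.16 log2). The others among the 12 largest outside the clock list, at a mean of at least 10 RPKM, were Tsc22d3, Serpina3b, Fam46b, Zbtb16, Top2a, Cdca3, Txnip, Serpinb12 and Akr1c18. In the glycolysis list 12 of 17 genes were called, and 13 adjusted over the list alone (Fisher's exact test, adjusted p = 0.0197). Among them were Pfkp (0.42 ± 0.07 log2, ZT20.6), Ldha (0.46 ± 0.08 log2, ZT18), Eno1 (ZT21.8) and Gpi1 (ZT11.5). The mean of the glycolysis list varied by 0.18 ± 0.07 log2 and did not pass its test (permutation test, adjusted p = 0.137). Members of the hair follicle and sebaceous gland list were called less often than other genes (1 of 18, Lhx2, and 0 adjusted over the list alone; 4 by limma at an unadjusted p under 0.05; adjusted p = 0.0419). So were members of the immediate early list (1 of 18, Klf4, and 1 adjusted over the list alone; adjusted p = 0.0419). The median fitted rhythms of these 2 lists, 0.56 and 0.48 log2, lay above the 0.23 log2 of all tested genes. Fewer calls thus do not mean smaller fitted rhythms.

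In all, limma called 4174 of 12144 genes in WT (34.4%), 922 of them with at least 1.5-fold between peak and trough. The deposited JTK_CYCLE q values of the authors called 2521 of the genes, of which 2511 were also called here, and 1174 passed both of the authors' methods. Of the called genes, 47.8% peaked between ZT18 and ZT24. After median-of-ratios rescaling of the libraries that share was 30.5%, with 3860 genes called, so the split of peaks between times of day depends on the scaling.

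RERE epidermis, with the clock restored in brain and skin, showed whether both together bring the rhythms back. Per2 varied by 5.57 ± 0.37 log2 with a peak at ZT13.1 (adjusted p = 3.11e-09), Dbp by 5.56 ± 0.32 log2 at ZT10.4, Nr1d1 by 3.95 ± 0.16 log2 at ZT7.88 and Arntl by 2.16 ± 0.16 log2 at ZT22.5. Of the 18 core clock genes 16 were called (18 adjusted over the list alone; adjusted p = 2.31e-10). The S phase list had 24 of 29 members called (25 adjusted over the list alone; adjusted p = 7.92e-14), with the list mean peaking at ZT12.8. The mitosis list had 28 of 28 (28 adjusted over the list alone; adjusted p = 2.16e-21), with the list mean peaking at ZT23.1 (permutation test, adjusted p = 7.2e-04). Further genes with large rhythms were Sprr2a3, a precursor of the cornified envelope (2.07 ± 0.40 log2, ZT3.69), the chemokine gene Cxcl14 (1.72 ± 0.16 log2, ZT23.4) and Ccnd2, which encodes cyclin D2 (1.62 ± 0.10 log2, ZT9.67). Limma called 1993 genes (16.4%), 505 of them at 1.5-fold or more. The authors' JTK_CYCLE q values called 1035, with 1030 in common, and 186 passed both of their methods. Of the 6 h spans from ZT0, ZT6, ZT12 and ZT18, ZT0 to ZT6 held the most peaks (42.2%). After rescaling it was ZT12 to ZT18 (33.9%).

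EpiRE epidermis has a clock in the skin without one in the brain, and showed small clock rhythms. Per2 varied by 2.15 ± 0.47 log2 or 4.43-fold with a peak at ZT9.91 (adjusted p = 0.0336), Dbp by 1.92 ± 0.44 log2 at ZT8.67 (adjusted p = 0.039), Per3, a further period gene, by 1.48 ± 0.26 log2 at ZT10.3 (adjusted p = 0.0171) and Arntl by 0.76 ± 0.15 log2 at ZT22 (adjusted p = 0.0222). Tef, Cry2 and Ciart completed the 7 of 18 core clock genes called (12 adjusted over the list alone; adjusted p = 4.43e-06). Nr1d1 was not called (1.01 ± 0.31 log2, adjusted p = 0.127). Replication and S phase genes were rhythmic as well, with 18 of 29 called (27 adjusted over the list alone; adjusted p = 7.22e-20). Mcm2 varied by 0.99 ± 0.20 log2 with a peak at ZT13, Lig1, the replicative DNA ligase, by 0.87 ± 0.14 log2 at ZT12.8, and Uhrf1, which maintains DNA methylation, by 1.08 ± 0.21 log2. In the mitosis list limma called 0 of 28, and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. Top2a varied by 0.17 ± 0.25 log2 and Ube2c by 0.20 ± 0.22 log2, and the list mean by 0.08 ± 0.23 log2 (permutation test, adjusted p = 0.941).

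Limma called 349 genes in EpiRE (2.87%), 80 of them at 1.5-fold or more, and 2485 had an unadjusted p under 0.05. The authors' JTK_CYCLE q values called 19, all of them called here. Their BIOCYCLE q values called 0, the smallest being 0.0987. Among the 6 h spans from ZT0, ZT6, ZT12 and ZT18, ZT12 to ZT18 held the most called genes (52.4%, and 46.1% after rescaling). These calls lie near the threshold. Without replicate number 1, 2, 3 or 4 the adjusted p of the Arntl rhythm in EpiRE was 0.121, 0.0722, 0.0574 or 0.147, and that of the Dbp rhythm in EpiRE 0.0844, 0.162, 0.0788 or 0.26. The count was 225 without EpiRE ZT0 replicate 4, 190 without ZT4 replicate 1, 227 without ZT12 replicate 1, 211 without ZT16 replicate 1, 550 without ZT16 replicate 3 and 214 without ZT16 replicate 4.

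BRE epidermis, which has no working clock of its own under a brain with one, showed many rhythms outside the clock. Replication and S phase genes were rhythmic, with their peak near lights on. Of 29 genes 25 were called (27 adjusted over the list alone; adjusted p = 1.57e-14), the list mean peaking at ZT1.04 (0.69 ± 0.14 log2, permutation test, adjusted p = 0.00262). The mean of 7 T cell genes peaked near that time (ZT23.8, 0.85 ± 0.24 log2, adjusted p = 0.0333). Mcm2 varied by 1.07 ± 0.23 log2 with a peak at ZT0.162, and Lig1, the replicative DNA ligase, by 0.82 ± 0.17 log2 at ZT1.41. Large rhythms were also seen in Fkbp5 (2.03 ± 0.43 log2, ZT14.4), Sprr2a3 (1.99 ± 0.31 log2, ZT3.88), F3, the gene of tissue factor (1.59 ± 0.29 log2, ZT12), and Glul (1.41 ± 0.20 log2, ZT14.1).

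Further lists were called in BRE. Keratinocyte differentiation had 12 of 27 members called (15 adjusted over the list alone; adjusted p = 0.00654), such as Ivl, the cornified envelope protein involucrin (1.12 ± 0.23 log2, ZT14.1), Aloxe3, an epidermal lipoxygenase (0.98 ± 0.20 log2, ZT13.1), and Spink5, a protease inhibitor of the skin barrier (0.80 ± 0.18 log2, ZT13.6). Oxidative phosphorylation had 16 of 28 (22 adjusted over the list alone; adjusted p = 2.25e-05), with smaller rhythms such as Ndufs1 of complex I (0.28 ± 0.04 log2, ZT0.291) and Atp5b of the ATP synthase (0.25 ± 0.05 log2, ZT3.07). The means of these lists peaked at ZT12.1 (0.54 ± 0.14 log2, permutation test, adjusted p = 0.0181) and at ZT4.15 (0.22 ± 0.05 log2, adjusted p = 0.00984). Median-of-ratios rescaling shifts BRE libraries by -0.09 to 0.07 log2, which is not small beside the latter. With it, genes called in BRE with a peak between ZT0 and ZT6 fell from 1170 to 545. Fisher's exact tests of lists and permutation tests of list means were not repeated after rescaling in any genotype or comparison. Of the mitosis list 2 of 28 were called, Ttk (adjusted p = 0.0158) and Bub1 (adjusted p = 0.0475), with 1 when adjusted over the list alone and 13 at an unadjusted p under 0.05.

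Few core clock genes were called in BRE. Per2 varied by 0.48 ± 0.31 log2 (adjusted p = 0.474), Nr1d1 by 0.15 ± 0.11 log2 (adjusted p = 0.573) and Dbp by 0.16 ± 0.15 log2 (adjusted p = 0.724). Larger fitted values that were not called were those of Per1 (0.80 ± 0.36 log2, adjusted p = 0.247), Nfil3 (0.73 ± 0.35, adjusted p = 0.281), Bhlhe40 (0.68 ± 0.39, adjusted p = 0.402) and Ciart (0.60 ± 0.24, adjusted p = 0.165). Of 18 genes 2 were called, and 2 adjusted over the list alone. These were Npas2 (0.34 ± 0.09 log2, adjusted p = 0.0289) and Arntl (0.18 ± 0.05 log2, adjusted p = 0.0329). The Arntl rhythm in BRE had adjusted p = 0.139 after median-of-ratios rescaling, and the Npas2 rhythm in BRE had adjusted p = 0.0756, 0.139, 0.107 and 0.0762 without replicate numbers 1, 2, 3 and 4. Limma called 2072 genes in BRE (17.1%), 416 of them at 1.5-fold or more. The authors' JTK_CYCLE q values called 689, of which 683 were called here, and their BIOCYCLE q values 0 (smallest 0.0725). Peaks lay between ZT0 and ZT6 for 56.5% of called genes, and for 35.3% after rescaling.

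**Figure D2:**
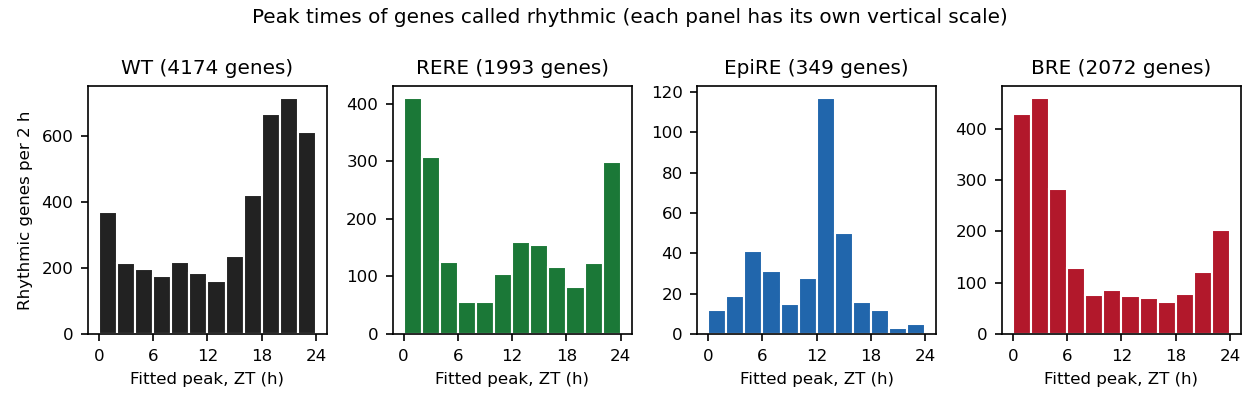
Number of genes called rhythmic per 2 h of fitted peak zeitgeber time (h), as bars, for each genotype on its own vertical scale. Only the 6 h spans ZT0 to ZT6, ZT6 to ZT12, ZT12 to ZT18 and ZT18 to ZT24 were compared. The fullest of them is ZT18 to ZT24 in WT (47.8% of 4174 genes) and ZT12 to ZT18 in EpiRE (52.4% of 349). In RERE (42.2% of 1993) and BRE (56.5% of 2072) it is ZT0 to ZT6. After rescaling of the libraries the shares of these fullest spans are 30.5% in WT, 29.6% in RERE, 35.3% in BRE and 46.1% in EpiRE. The fullest of the compared spans in RERE is then ZT12 to ZT18 (33.9%). Spans that start at other times can hold more. In RERE the fullest bars are ZT0 to ZT2 (410 genes), ZT2 to ZT4 (307) and ZT22 to ZT24 (299). In EpiRE the bar ZT10 to ZT12 holds 28 genes and ZT16 to ZT18 holds 16.

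BRE and WT differ in the clock of the epidermis and of other tissues outside the brain. Nr1d1 had the smallest adjusted p of all genes (2.49e-21), with 4.03 ± 0.14 log2 in WT against 0.15 ± 0.11 in BRE, and 15 of 18 core clock genes differed (16 adjusted over the list alone; adjusted p = 1.31e-07). Outside the clock, Ttc9, a tetratricopeptide gene, went from 2.30 ± 0.14 log2 to 0.09 ± 0.09 (adjusted p = 7.32e-13), Sod2, the mitochondrial superoxide dismutase, from 0.55 ± 0.03 to 0.05 ± 0.05 (adjusted p = 4.85e-09), and the chemokine gene Cx3cl1 from 1.06 ± 0.06 to 0.21 ± 0.10 (adjusted p = 7.4e-10). Ccnd2 (chromosome 6, 127125162 to 127152193, minus strand) went from 1.59 ± 0.16 log2 to 0.37 ± 0.10 (adjusted p = 1.35e-09). Pdxk, the kinase that activates vitamin B6, went from 1.20 ± 0.07 log2 to 0.31 ± 0.09 (adjusted p = 4.5e-10). Leo1, Tns4 and Ptpa were also among the 12 smallest p-values outside the clock list.

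Other genes were rhythmic in both WT and BRE with peaks far apart. Tk1, the thymidine kinase of S phase, varied by 0.83 ± 0.07 log2 with a peak at ZT16.7 in WT and by 0.89 ± 0.14 log2 at ZT3.2 in BRE (adjusted p = 4.5e-10). Mthfd1l, an enzyme of mitochondrial folate metabolism, peaked at ZT13.7 in WT and at ZT1.07 in BRE (adjusted p = 2.81e-10), and Rnaseh2b and Dscc1 moved likewise. Rhythms differed for 28 of 29 S phase genes (28 adjusted over the list alone; adjusted p = 1.84e-17) and 27 of 28 mitosis genes (28 adjusted over the list alone; adjusted p = 4.43e-17). They also differed for 13 of 28 oxidative phosphorylation genes (15 adjusted over the list alone; adjusted p = 0.00769), such as Atp5o (adjusted p = 0.000516) and Ndufa4 (adjusted p = 0.000885), and for 12 of 19 antioxidant targets of Nrf2 (12 adjusted over the list alone; adjusted p = 0.000332), such as Taldo1 (adjusted p = 0.00288) and Gclm (adjusted p = 0.00474). In the fasting list 9 of 18 differed (9 adjusted over the list alone; adjusted p = 0.0183), such as Hadha of fatty acid oxidation (adjusted p = 3.66e-05) and Ucp2 (adjusted p = 5.18e-05). In all 2457 genes differed (20.2%), with the larger rhythm in WT for 1778 and in BRE for 679.

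EpiRE and WT differ in the clock of the brain and of other tissues outside the epidermis. Core clock rhythms were smaller, with 14 of 18 genes differing (14 adjusted over the list alone; adjusted p = 2.57e-11), among them Per2 (adjusted p = 3.81e-06) and Nr1d1 (adjusted p = 9.92e-07). Mitosis genes differed in 26 of 28 cases (27 adjusted over the list alone; adjusted p = 8.78e-25), and Nuf2, a kinetochore gene outside the list, went from 1.55 ± 0.16 log2 in WT to 0.27 ± 0.21 in EpiRE (adjusted p = 0.000199). S phase genes differed in 3 of 29 cases, Ccne2 (adjusted p = 0.00147), Rrm2 (adjusted p = 0.00244) and Pola1 (adjusted p = 0.0218), with 6 adjusted over the list alone (adjusted p = 1). Ptpa, an activator of protein phosphatase 2A, went from 0.39 ± 0.03 log2 to 0.05 ± 0.03 (adjusted p = 1.74e-05), Sod2 from 0.55 ± 0.03 to 0.20 ± 0.05 (adjusted p = 9.35e-05), and Ugt1a6a, a glucuronosyltransferase, from 0.75 ± 0.07 to 0.13 ± 0.10 (adjusted p = 0.000138). The remaining genes of the 12 with the smallest p-values outside the clock list were Leo1, Pdxk, Rgs3, Naa60, Aaas, Dpy19l1, Trappc9 and Rasa3. Rhythms of 1034 genes differed (8.51%), 939 of them larger in WT and 95 larger in EpiRE. With median-of-ratios rescaling the count was 647.

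Between RERE and WT, which tests how complete the restored rhythms are, 55 genes differed (0.453%), 47 with the larger rhythm in WT. By limma 1659 of 12144 genes had an unadjusted p under 0.05, and 1993 genes were called in RERE against 4174 in WT. The 55 therefore leave room for many smaller differences. Adrm1, a ubiquitin receptor of the proteasome, varied by 0.22 ± 0.04 log2 with a peak at ZT17.9 in WT and by 0.20 ± 0.05 log2 at ZT7.15 in RERE (adjusted p = 0.000754). Slc35a4 peaked at ZT20.3 in WT and at ZT4.7 in RERE (adjusted p = 0.0123). Psmc4, a proteasome ATPase, varied by 0.33 ± 0.04 log2 in WT and 0.07 ± 0.04 in RERE (adjusted p = 0.0463), Tomm40, the import pore of mitochondria, by 0.47 ± 0.07 and 0.15 ± 0.07 (adjusted p = 0.0457), and Eif3b, a translation initiation factor, by 0.30 ± 0.05 and 0.09 ± 0.03 (adjusted p = 0.0318). The other genes named by rule were Kti12, Pik3cb, Cnpy3, Gps1, Slc25a39, Rexo2 and Ppfibp2. In the core clock list limma found 0 of 18 (0 adjusted over the list alone), with 2 at an unadjusted p under 0.05. It found 0 of 29 S phase genes (3 adjusted over the list alone, 9 unadjusted) and 0 of 28 mitosis genes (0 adjusted over the list alone, 0 unadjusted). In the oxidative phosphorylation list Cyc1 (adjusted p = 0.0488) and Atp5b (adjusted p = 0.0493) differed, and 10 of 28 adjusted over the list alone (adjusted p = 0.169). A difference of 1.5-fold was found for 61.2% of simulated genes, so small differences would be missed. The count was 10 after median-of-ratios rescaling, between 0 and 2 without any replicate number, and between 2 (without WT ZT4 replicate 1, among others) and 191 (without RERE ZT16 replicate 2) when a library was removed.

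Between RERE and EpiRE, which differ in the brain clock alone, core clock rhythms were larger in RERE. Per2 varied by 5.57 ± 0.37 log2 against 2.15 ± 0.47 (adjusted p = 8.51e-05) and Nr1d1 by 3.95 ± 0.16 log2 against 1.01 ± 0.31 (adjusted p = 1.35e-06), with 13 of 18 clock genes differing (15 adjusted over the list alone; adjusted p = 5.65e-14). Mitosis genes differed in 21 of 28 cases (26 adjusted over the list alone; adjusted p = 7.93e-23). In the S phase list limma found 0 of 29 (0 adjusted over the list alone), with 1 at an unadjusted p under 0.05. Plxnd1, a semaphorin receptor, varied by 2.00 ± 0.18 log2 in RERE and 0.51 ± 0.15 in EpiRE (adjusted p = 0.00015), Ttc9 by 2.18 ± 0.11 and 0.98 ± 0.16 (adjusted p = 0.000365), and Gas6, a ligand of the TAM receptor kinases, by 0.33 ± 0.04 and 0.02 ± 0.03 (adjusted p = 0.000365). Mab21l3, Cgrrf1, Sod2, Prag1, Ptpa, Duxbl1, Foxn3, Trmt2b and Tspear completed the 12 genes with the smallest p-values outside the clock list. The count was 491 (4.04%), with 412 rhythms larger in RERE and 79 larger in EpiRE.

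Between RERE and BRE, which differ in the epidermal clock, 14 of 18 clock genes differed (15 adjusted over the list alone; adjusted p = 5.94e-15), Nr1d1 with adjusted p = 2.17e-19. S phase genes differed in 28 of 29 cases (28 adjusted over the list alone; adjusted p = 4.03e-35), with list means peaking at ZT12.8 in RERE and ZT1.04 in BRE, and mitosis genes in 25 of 28 (27 adjusted over the list alone; adjusted p = 2.15e-29). Ccnd2 varied by 1.62 ± 0.10 log2 in RERE and 0.37 ± 0.10 in BRE (adjusted p = 1.97e-13), Cxcl14 by 1.72 ± 0.16 and 0.15 ± 0.08 (adjusted p = 1.5e-07), and Ttc9 by 2.18 ± 0.11 and 0.09 ± 0.09 (adjusted p = 1.29e-14). Arsi, an arylsulfatase gene, peaked at ZT9.04 in RERE and ZT19.2 in BRE (adjusted p = 1.31e-08). The rule also named Mthfd1l, Fam234b, Tmem57, Sod2, Acsl5, Rbms1 and Hs3st6. In the oxidative phosphorylation list limma found 0 of 28 (0 adjusted over the list alone, 0 at an unadjusted p under 0.05). The total was 582 genes (4.79%), 401 with the larger rhythm in RERE and 181 in BRE.

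EpiRE and BRE each hold a clock in only 1 of the 2 tissues. S phase genes were rhythmic in both, with opposite peaks. Their rhythms differed in 28 of 29 cases (28 adjusted over the list alone; adjusted p = 5.37e-22). Lig1 peaked at ZT12.8 in EpiRE and ZT1.41 in BRE (adjusted p = 3.5e-05), Tk1 at ZT13 and ZT3.2 (adjusted p = 2.38e-05), and Topbp1, a scaffold of replication initiation, at ZT13.1 and ZT0.283 (adjusted p = 2.38e-05). Chaf1b, Rnaseh2b, Mthfd1l, Cdk2, Chtf18, Pola1, Dscc1 and Cyb5r1 were among the others of the 12 genes with the smallest p-values outside the clock list. Of the mitosis list 1 of 28 differed, Ttk (adjusted p = 0.0107), also adjusted over the list alone. Core clock rhythms differed for 7 of 18 genes (11 adjusted over the list alone; adjusted p = 0.0471), such as Per3 (adjusted p = 0.00117). Oxidative phosphorylation differed in 13 of 28 genes (16 adjusted over the list alone; adjusted p = 0.000414), such as Ndufv1 (adjusted p = 0.00604) and Atp5b (adjusted p = 0.00821), and the basal keratinocyte list in 7 of 13 (8 adjusted over the list alone; adjusted p = 0.00639). The latter included the integrin gene Itga6 (adjusted p = 0.00761) and Col17a1, a collagen of hemidesmosomes (adjusted p = 0.0181). The total was 1692 genes (13.9%), with the larger rhythm in BRE for 1277 and in EpiRE for 415.

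**Figure D3:**
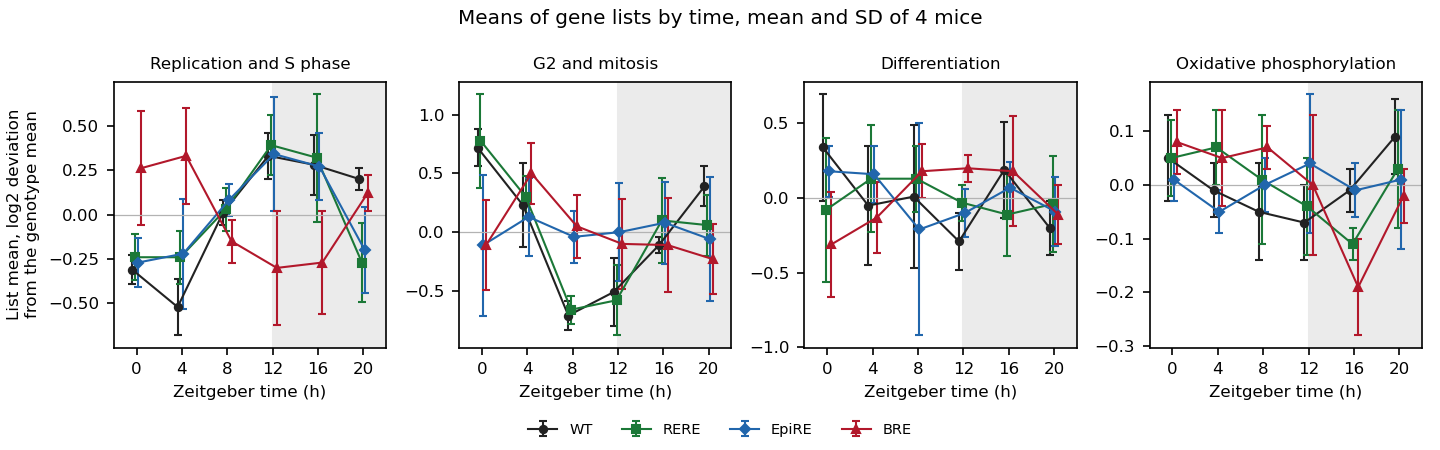
Mean log2 deviation from the genotype mean of 4 gene lists against zeitgeber time (h), as mean ± SD of 4 mice per genotype. The S phase list peaks near ZT14.8 in WT, ZT12.8 in RERE, ZT12.7 in EpiRE and ZT1.04 in BRE, and the mitosis list varies by 1.37 log2 in WT against 0.08 in EpiRE.

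Genes were then grouped by which genotypes shared a rhythm. Of 7666 genes assigned to a model, 2859 (37.3%) had no rhythm in any genotype. The most frequent rhythmic model, with 1022 genes (13.3%), held the same rhythm in WT, RERE and BRE and none in EpiRE. At a minimum of 1.5-fold between peak and trough it fell behind the class of WT and RERE alone, and without replicate number 2 it held 508 genes. Its highest weights included Limch1, an actin regulator (0.77 ± 0.11, 0.76 ± 0.10, 0.05 ± 0.13 and 0.67 ± 0.14 log2 in WT, RERE, EpiRE and BRE), and Tnfrsf19, a receptor of the TNF family (0.40 ± 0.07, 0.43 ± 0.07, 0.10 ± 0.11 and 0.46 ± 0.10 log2), with Cox15, Wdr44, Rnf141 and Ddx58. A rhythm shared by WT and RERE alone was assigned to 562 genes, such as Thoc2 of the mRNA export complex THO (0.32 ± 0.06, 0.30 ± 0.05, 0.04 ± 0.05 and 0.04 ± 0.05 log2), Nsmce3, Rnf26, Prr11, Ccdc18 and Jarid2. A rhythm shared by WT, RERE and EpiRE was assigned to 408 genes, such as the small GTPase gene Rras (0.43 ± 0.10, 0.43 ± 0.10, 0.40 ± 0.10 and 0.17 ± 0.11 log2), Uso1, Blzf1, Hdgfrp3, Cr1l and Stk24. In 308 genes all 4 genotypes shared it, such as Ptbp3, an RNA-binding protein (0.22 ± 0.06, 0.26 ± 0.06, 0.29 ± 0.06 and 0.21 ± 0.05 log2), Tusc3, Chm, Cct5, Ppp1r2 and Ascc3. These groupings carry no p-value, and in simulated data 35.7% of the genes put in the class of WT and RERE did not belong there. That share need not hold in the real data, where many more genes were rhythmic. The groupings, that of WT, RERE and BRE among them, were not computed again after median-of-ratios rescaling. With it, 3411 of 4174, 1578 of 1993, 301 of 349 and 1316 of 2072 genes called in WT, RERE, EpiRE and BRE were still called.

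Genes called at an adjusted p below 0.05 in any pair of genotypes overlapped beyond chance (Fisher's exact test). Below 0.01 this held for every pair except EpiRE and BRE, which shared 3 genes where 1.01 were expected (odds ratio 3.25, exact p = 0.0776). WT and RERE shared 1418 genes where 685 were expected (odds ratio 6.62, exact p = 5.96e-298), and WT and EpiRE shared 237 where 120 were expected (4.22, exact p = 3.41e-38). For WT and BRE 1050 were shared and 712 expected (odds ratio 2.28, exact p = 2.86e-63), for RERE and EpiRE 150 and 57.3 (4.07, exact p = 8.73e-33), for RERE and BRE 682 and 340 (3.28, exact p = 4.83e-95), and for EpiRE and BRE 139 and 59.5 (3.38, exact p = 1.2e-24). Among shared genes the median peak was 0.87 h later in RERE than in WT (jackknife SE 0.48 h), with an amplitude ratio of 0.913. EpiRE differed from WT by -2.23 h (SE 1.29 h; amplitude ratio 0.805), and BRE peaked 3.90 h later than WT (SE 1.06 h; ratio 0.933), with 329 of the 1050 shared genes more than 6 h apart. All these ratios leave out rhythms too small to be called in 1 of the genotypes. Over all tested genes the median rhythm was 0.23, 0.18, 0.15 and 0.20 log2 in WT, RERE, EpiRE and BRE. The core clock list mean varied by 1.52, 1.42, 0.49 and 0.24 log2. Against RERE the median shift was -0.93 h in EpiRE (SE 1.10 h; ratio 0.891) and 1.12 h in BRE (SE 1.01 h; ratio 0.986). From EpiRE to BRE it was 11.03 h (SE 6.11 h; ratio 1.02), and 3.43 h over the 3 genes called in both at an adjusted p under 0.01. With 1 replicate number left out at a time, as behind these SE, it rests on 1 to 13 genes in place of 139. That of RERE and EpiRE rests on 3 to 96 in place of 150, and that of WT and EpiRE on 4 to 201 in place of 237. That of RERE and BRE rests on 58 to 316 in place of 682. For WT and BRE the numbers are 80 to 755 in place of 1050, and for WT and RERE 565 to 788 in place of 1418. Peak shifts and ratios were not computed again after median-of-ratios rescaling.

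The lists of signals that reach skin from the body were compared next. Both cold-inducible RNA-binding genes, which respond to small falls in temperature, were called in WT, RERE and BRE, but as a list they did not pass Fisher's exact test in any genotype (adjusted p = 0.218, 0.162, 1 and 0.116 in WT, RERE, EpiRE and BRE). Rbm3 varied by 0.80 ± 0.15 log2 with a peak at ZT8.44 in WT and by 0.89 ± 0.10 log2 at ZT6.12 in BRE. Cirbp varied by 0.74 ± 0.19 log2 in WT and 1.01 ± 0.19 in BRE. In EpiRE limma called 0 of 2 (1 adjusted over the list alone, 1 at an unadjusted p under 0.05), and both differed between EpiRE and BRE (Rbm3 adjusted p = 0.0089, Cirbp adjusted p = 0.0221). Limma called 0 of 2 in the differences of EpiRE from WT (2 adjusted over the list alone, 2 unadjusted) and from RERE (0 and 1). The glucocorticoid list had 5 of 14 members called in WT, 5 in RERE, 0 in EpiRE (2 unadjusted) and 3 in BRE (5, 9, 0 and 5 adjusted over the list alone), and passed Fisher's exact test in none of them (adjusted p = 1, 0.223, 1 and 0.943). Its mean varied by 0.94 ± 0.24 log2 in WT (ZT10.8, permutation test, adjusted p = 0.0121), by 0.88 ± 0.22 in RERE (adjusted p = 0.0175), by 0.22 ± 0.18 in EpiRE (adjusted p = 0.554) and by 0.58 ± 0.18 in BRE (ZT14.5, adjusted p = 0.045). Differences were called for 1 of 14 between EpiRE and WT, Klf9 (adjusted p = 0.0281), 1 between EpiRE and BRE, Cdkn1a (adjusted p = 0.0307), and by limma 0 between RERE and EpiRE (1 unadjusted), the same numbers as when adjusted over the list alone. The list passed in none of these (adjusted p = 1 in each). Fkbp5 was not called in the difference between EpiRE and BRE (adjusted p = 0.101). The heat shock list had 11, 6, 2 and 8 of 20 members called in WT, RERE, EpiRE and BRE (11, 7, 5 and 9 adjusted over the list alone), including the chaperones Pdia6 (0.77 ± 0.10 log2, ZT20.3), Hspd1 and Hsp90b1 in WT. It passed Fisher's exact test in none of them (adjusted p = 0.182, 0.269, 0.892 and 0.0679).

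Metabolic and repair lists passed no Fisher's exact test of called members within a genotype beyond those given above. Fasting and lipid oxidation had 10, 6, 0 and 5 of 18 members called in WT, RERE, EpiRE and BRE (10, 8, 2 and 9 adjusted over the list alone; 5 unadjusted in EpiRE). Cholesterol and fatty acid synthesis had 7, 5, 0 and 3 of 24 (7, 6, 0 and 3 adjusted over the list alone; 2 unadjusted in EpiRE), such as Acaca, the committed enzyme of fatty acid synthesis (0.69 ± 0.09 log2, ZT22.6 in WT). Antioxidant targets of Nrf2 had 9, 6, 0 and 6 of 19 (12, 9, 0 and 9 adjusted over the list alone; 4 unadjusted in EpiRE), their mean peaking at ZT20.8 in WT (permutation test, adjusted p = 0.0333) and ZT4.48 in BRE (adjusted p = 3.2e-04). Excision repair had 6, 2, 1 and 0 of 16 (6, 6, 1 and 0 adjusted over the list alone; 6 unadjusted in BRE), with Polh, a polymerase that copies past ultraviolet damage, at 0.50 ± 0.09 log2 in WT. Glycolysis had 4, 1 and 2 of 17 in RERE, EpiRE and BRE (5, 2 and 7 adjusted over the list alone). Oxidative phosphorylation had 14, 8 and 0 of 28 in WT, RERE and EpiRE (15, 9 and 0 adjusted over the list alone; 3 unadjusted in EpiRE). Clock output genes shared across tissues had 9, 5, 1 and 0 of 13 in WT, RERE, EpiRE and BRE (9, 6, 1 and 0 adjusted over the list alone; 2 unadjusted in BRE), among them Lonrf3 and Slc46a3 in WT. Immediate early genes had 1, 0 and 0 of 18 in RERE, EpiRE and BRE (7, 0 and 0 adjusted over the list alone; 10, 1 and 3 unadjusted).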

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

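The tests of shifted time labels and of the shares of cell types were chosen only after the results were seen. The tests of scaling, depth, gene length and permuted labels were set down before theirs.

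Replication and S phase genes peaked 11.7 h (SE 1.07 h) apart in EpiRE and BRE epidermis, by the means of the list per library. Wrong time labels are argued against as the whole cause by genes outside both cell cycle lists, whose median peak lay 3.75 h later in BRE than in WT (1024 genes, quartiles 1.43 and 6.42 h) and differed by -2.24 h in EpiRE (220 genes, quartiles -3.74 and -1.16 h), while from EpiRE to BRE it differed by 9.65 h (122 genes, quartiles 2.74 and 12.55 h) with 53 of them within 6 h, where labels shifted by 12 h would move all alike. The authors' scaling is argued against by a gap of 11.8 h (SE 1.10 h) after median-of-ratios rescaling, and sequencing depth by a gap of 11.6 h (SE 1.13 h) with depth in the fit. Changing shares of basal or differentiated keratinocytes are argued against as the whole cause: from trough to peak of the S phase list its mean rose by 0.67 ± 0.13 log2 in EpiRE and 0.69 ± 0.14 in BRE, but the median of 13 basal genes rose by 0.06 (SD 0.10) and 0.11 (SD 0.19), and that of 7 genes of Langerhans and dendritic cells, which fewer differentiated cells would raise as much, changed by -0.25 (SD 0.12) and 0.13 (SD 0.14). The 27 differentiation genes themselves changed by a median of -0.31 (SD 0.32) in EpiRE and -0.54 (SD 0.44) in BRE. That is the direction a falling share of differentiated cells would give, so such a change stays open as part of the cause. A changing share of T cells is argued against in EpiRE, with a median change of 0.04 (SD 0.23, 7 genes). It stays open in BRE, where the median change was 0.85 (SD 0.28), from 0.26 for the most abundant, Thy1, at 53.8 RPKM, to 1.12. Fitted rhythms of the T cell list mean were of similar size in WT (0.79 ± 0.32 log2, ZT21.9) and RERE (0.64 ± 0.33 log2, ZT22.9), where the S phase list mean peaked at ZT14.8 and ZT12.8. As these T cell rhythms did not pass the permutation test (adjusted p = 0.137 and 0.276), they do not decide the question for BRE. Also open is the untested biological explanation that the brain clock and the epidermal clock may each time replication differently.

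Of the 4174 genes called in WT, 1995 peaked between ZT18 and ZT24. Gene length bias is argued against as the whole cause, since 1735 such genes were called with each library's length slope in the fit (3856 called in all), and so is depth, with 1991 (4096 called). The authors' scaling is likely to carry part of the pattern and stays open as its main cause, since 1177 such genes were called after median-of-ratios rescaling, or 30.5% of 3860 in place of 47.8%. The bound set for it beforehand, 998 genes, was ill chosen, since peaks spread evenly over the day would put 965 there. No biological explanation was tested.

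Rhythms that differed between genotypes by the test of the difference itself numbered 2457 genes for BRE against WT, 1034 for EpiRE against WT, 55 for RERE against WT, 491 for RERE against EpiRE, 582 for RERE against BRE and 1692 for EpiRE against BRE. Of 100 assignments of the libraries to genotypes within time points, the real one included, only 1 gave as many genes in each comparison, the real one. Differences in level and rhythm between genotypes stay in the residuals of the other assignments and can lower their counts. The result argues against genotype labels that make no difference at all, but cannot exclude chance for rhythms alone. The RERE against WT count also fell to between 0 and 2 without any 1 replicate number. The highest counts of the other assignments, in the same order, were 1, 0, 7, 6, 183 and 1. With time labels permuted, no other assignment gave as many as the 4174 genes called in WT (highest other 6), the 1993 in RERE (65), the 349 in EpiRE (3), the 2072 in BRE (6) and the 4807 genes given a rhythmic model (1244). This argues against chance for these counts as a whole.

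Some libraries stood far from the 3 others of their genotype and time. Among 168 groups tested by Dixon's criterion over 7 measures, 12 had such a library, where chance gives about 8.4 (1 in 20). Depth was 12.2 M reads in EpiRE ZT4 replicate 2 (others 18.5 M to 19.1 M), 13.7 M in EpiRE ZT16 replicate 4 (18.3 M to 18.6 M) and 12.9 M in BRE ZT20 replicate 1 (17.8 M to 18.3 M). Among clock genes, log2 Arntl was 3.72 in BRE ZT12 replicate 3 (3.51 to 3.54), log2 Nr1d1 was 6.31 in WT ZT12 replicate 3 (6.08 to 6.09) and 2.33 in BRE ZT4 replicate 3 (1.81 to 1.85). Log2 Dbp was 6.03 in EpiRE ZT8 replicate 4 (5.21 to 5.27), and log2 Per2 was 3.73 in WT ZT16 replicate 4 (3.43 to 3.46). The mean log2 deviation of the S phase list was 0.65 in RERE ZT12 replicate 4 (0.30 to 0.32). That of the mitosis list was 0.47 in WT ZT0 replicate 4 (0.77 to 0.81), 0.03 in RERE ZT4 replicate 1 (0.37 to 0.41) and 0.46 in BRE ZT0 replicate 4 (-0.33 to -0.23).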

How the results depend on the processing

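Removal of single libraries was added after seeing the data, and all other alternatives were planned. Median peak shifts of shared genes kept their sign at an adjusted p below 0.01 and without each replicate number, the only alternatives run for them. Neither these shifts nor the amplitude ratios were computed again after median-of-ratios rescaling, which moved the peak times of called genes. Amplitude ratios of shared genes, which carry no test, crossed 1 in 4 of 6 pairs. Called rhythms were followed for all list members and genes named by the rule, also those the text does not name. Of their values under the alternatives, 7323 stayed past the threshold and 2090 did not. Called rhythm differences were followed for genes named by the rule and for the core clock, S phase and mitosis lists. Of those values 5712 stayed past the threshold and 814 did not. Pseudocounts of 0.1 and 1 moved no count beyond 1.5 times. The mean-level comparisons, the tests of lists on mean levels and the count-based tools were not run, because the tables were normalized apart and hold no counts.

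Larger changes, by setting, were as follows, and except where the setting itself tests fewer genes or asks for more, the cause was not tested. Without the filter EpiRE had 208 called genes and RERE against WT 2. With a mean of at least 5 RPKM, which tests fewer genes, EpiRE against WT had 680 and RERE against BRE 364. After median-of-ratios rescaling EpiRE against WT had 647 and RERE against WT 10. Array weights gave 3272 genes in RERE, 621 in EpiRE, 3281 in BRE, 1670 for EpiRE against WT, 478 for RERE against WT, 1205 for RERE against EpiRE and 1077 for RERE against BRE. A fit on all 96 libraries gave 84 for RERE against WT. Replicate number as a block gave 206 in EpiRE and 4 for RERE against WT, where libraries of the same number had a mean r of -0.001 within a genotype and those of other numbers 0.001, and 22 lay closest to their own number where chance gives 24. Time as a 6-level factor gave 1306 in RERE, 1584 for BRE against WT, 629 for EpiRE against WT, 17 for RERE against WT, 276 for RERE against EpiRE and 907 for EpiRE against BRE, and of the 4174, 1993, 349 and 2072 genes called in WT, RERE, EpiRE and BRE it also called 3238, 1074, 106 and 1109. A minimum of 1.5-fold left 922, 505, 80 and 416 genes in WT, RERE, EpiRE and BRE, and the authors' q values by both methods 1174, 186, 0 and 0. A BIC weight of 0.6 left 2184 genes with a rhythmic model, of which 109 shared it in all genotypes, 300 in WT and RERE, 555 in WT, RERE and BRE and 181 in WT, RERE and EpiRE, and a minimum of 1.5-fold left 1059, 22, 200, 164 and 60. At an adjusted p under 0.01 the overlap of EpiRE and BRE had an odds ratio of 3.25 (exact p = 0.0776), their peak shift was 3.43 h, and the amplitude ratio of BRE to WT was 1.02. Adjusted over the list alone, 54 list members were called in EpiRE in place of 30, and 28 differed between RERE and WT in place of 2.

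Without each replicate number in turn, which leaves fewer mice, the counts ranged from 2065 to 3663 in WT, 1034 to 1275 in RERE, 6 to 378 in EpiRE and 211 to 1820 in BRE. For the differences they ranged from 1012 to 1873 (BRE against WT), 145 to 1376 (EpiRE against WT), 0 to 2 (RERE against WT), 74 to 256 (RERE against EpiRE), 188 to 714 (RERE against BRE) and 383 to 1313 (EpiRE against BRE). Genes with a rhythmic model ranged from 3645 to 4373, the class of all genotypes from 223 to 280, that of WT and RERE from 430 to 607, that with BRE added from 508 to 1000 and that with EpiRE added from 284 to 401. Peak shifts and amplitude ratios ranged from 0.18 to 0.94 h and 0.88 to 0.98 (WT to RERE), -3.48 to -1.44 h and 0.81 to 0.95 (WT to EpiRE), 3.20 to 4.66 h and 0.98 to 1.10 (WT to BRE), -2.23 to -0.45 h and 0.84 to 1.19 (RERE to EpiRE), 0.49 to 2.07 h and 0.97 to 1.08 (RERE to BRE), and 3.44 to 11.84 h and 0.75 to 1.08 (EpiRE to BRE).

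Without single libraries the counts ranged from 3709 to 4544 in WT, 1617 to 2263 in RERE, 190 to 550 in EpiRE and 1445 to 2787 in BRE. For the differences they ranged from 2057 to 2949 (BRE against WT), 779 to 1421 (EpiRE against WT), 352 to 655 (RERE against EpiRE), 493 to 722 (RERE against BRE) and 1252 to 2337 (EpiRE against BRE). For RERE against WT 41 of 48 libraries moved the count of 55 by over 1.5 times. Without replicates 1 to 4 in turn, it was 4, 7, 31 and 14 for WT ZT0, 2, 2, 3 and 69 for WT ZT4, 96, 3, 12 and 74 for WT ZT8, 73, 13, 89 and 20 for WT ZT12, 83, 29, 16 and 3 for WT ZT16, and 3, 3, 3 and 147 for WT ZT20. In the same order it was 13, 26, 55 and 5 for RERE ZT0, 2, 13, 37 and 3 for RERE ZT4, 22, 143, 40 and 89 for RERE ZT8, 19, 11, 9 and 88 for RERE ZT12, 2, 191, 2 and 7 for RERE ZT16, and 81, 3, 18 and 3 for RERE ZT20. Genes called in every such fit numbered 1706, 640, 2, 291, 442 and 1053 for BRE against WT, EpiRE against WT, RERE against WT, RERE against EpiRE, RERE against BRE and EpiRE against BRE, the 2 being Adrm1 and Slc35a4.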

Other observations

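The correlations between mice at the end of this part, and the removal there of times and mice, were chosen after the spread between EpiRE mice had been seen, and the correlations belong to a family of 8 relations, 4 of which are given. Few genes of other cell types of the skin were called. The epidermis was dominated by keratinocytes, with means of 6.31e+03 RPKM for Krt5 and 3.16e+03 RPKM for Krt14 in WT. Of 7 tested T cell genes, 1 was called in WT and 1 in RERE (Thy1 in both), 0 in EpiRE by limma (0 at an unadjusted p under 0.05) and 2 in BRE (Cd3d, adjusted p = 0.0332, and Il2rb, adjusted p = 0.0414), with 1, 1, 0 and 5 adjusted over the list alone. Thy1, a surface protein of dendritic epidermal T cells, varied by 1.22 ± 0.14 log2 with a peak at ZT23 in WT. Of 7 genes of Langerhans and dendritic cells limma called 0 in any genotype (0 adjusted over the list alone, and 0, 0, 0 and 1 at an unadjusted p under 0.05 in WT, RERE, EpiRE and BRE). It also called 0 of 4 melanocyte genes (0 adjusted over the list alone, and 1, 1, 1 and 0 unadjusted). The most abundant of them in WT, Dct, had a mean of 5.07 RPKM there and 1.47, 1.46 and 2.02 RPKM in RERE, EpiRE and BRE. Pmel was also higher in WT (3.88 against 2.5, 2.42 and 2.31 RPKM), while Tyr (3.98 against 4.19, 4.12 and 3.91) and Mitf (2.24 against 2.08, 2.07 and 1.87) lay closer. Some growing hair and fibroblast markers were also higher in WT, such as Hoxc13 (2.79 against 1.24, 1.41 and 1.34 RPKM) and Fbln1 (3.18 against 1.61, 1.65 and 1.49). Others of these lists lay closer, such as Msx2 (5.1 against 5.04, 5.01 and 5.07) and Col6a1 (4.74 against 4.67, 4.95 and 5.27). Cd207 of Langerhans cells was lower in WT (2.24 against 3.08, 3.46 and 3.98), but Csf1r was close (4.27 against 4.49, 4.41 and 4.67). Whether WT samples held more melanocytes or otherwise differed in their mix of cells, which would touch comparisons with WT, was not tested. Of 4 fibroblast genes 1, Fbln1, was called in WT (1.41 ± 0.40 log2) and 0 in the 3 other genotypes (1, 1 and 0 unadjusted), with 3, 0, 1 and 0 adjusted over the list alone. Of 2 skeletal muscle genes, Acta1 and Mylpf, and of 2 blood genes limma called 0 in all 4 genotypes. For muscle 0, 0, 1 and 1 were called when adjusted over the list alone (0, 0, 1 and 1 unadjusted), with a list mean that varied by 0.38 ± 0.11 log2 in BRE (ZT17.9, permutation test, adjusted p = 0.0302), and for blood 0 (0 unadjusted). No endothelial or adipocyte gene was expressed enough to test.

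The basal list had 3, 2, 0 and 6 of 13 members called in WT, RERE, EpiRE and BRE (3, 2, 0 and 8 adjusted over the list alone; 1 at an unadjusted p under 0.05 in EpiRE by limma), and the differentiation list 5, 3, 0 and 12 of 27 (1, 3, 0 and 15 adjusted over the list alone; 1 unadjusted in EpiRE). In the difference of BRE from WT 6 and 9 members of these lists were called (10 and 11 adjusted over the list alone; Fisher's exact test, adjusted p = 0.103 and 0.208). From RERE 2 and 1 were called, Col17a1 (adjusted p = 0.00848), Dst (adjusted p = 0.0243) and Ivl (adjusted p = 0.0074), with 3 and 2 adjusted over the list alone (adjusted p = 0.505 and 1). Within BRE the basal list had adjusted p = 0.0679. Dst, a linker of hemidesmosomes, varied by 1.03 ± 0.10 log2 with a peak at ZT9.4 in WT. Hair follicle and sebaceous gland genes had 0, 0 and 2 of 18 called in RERE, EpiRE and BRE (0, 0 and 2 adjusted over the list alone; 1 and 3 unadjusted in RERE and EpiRE), those in BRE being Lgr6, a stem cell receptor, and Plin2, which coats lipid droplets. Markers of growing hair had 2, 1, 0 and 3 of 5 called (2, 1, 1 and 3 adjusted over the list alone; 2 unadjusted in EpiRE), the list mean varying by 0.46 ± 0.13 log2 in WT (ZT18.1, permutation test, adjusted p = 0.0227) and 0.25 ± 0.06 in BRE (ZT14.3, adjusted p = 0.0145). Trichohyalin, Tchh, was called in WT, RERE and BRE.

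Mean clock gene levels also lay far apart between BRE and WT, set side by side since the tables were normalized apart and levels were not tested between genotypes. Npas2 had a mean of 16.9 RPKM in BRE and 5.5 RPKM in WT, and Cry1 37.3 and 13.2 RPKM. Nr1d1 had 4.07 RPKM in BRE and 61.9 RPKM in WT, Dbp 4.27 and 38.6 RPKM, and Per3 2.19 and 11.4 RPKM. Arntl had 12.8 and 14.7 RPKM. These are means of RPKM over all times, which weigh the times of high levels most. Between means of log2 values the differences BRE minus WT were 0.02 log2 for Arntl and ran from -3.32 log2 for Nr1d1 to 1.95 log2 for Npas2, a spread of 5.27 log2, computed after the levels had been seen to set it against an offset shared by all genes, with a median over all genes of -0.05 log2.

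The mean deviation of Dbp, Tef, Per3, Cry2 and Ciart between mice of the same time had an SD of 0.44 log2 in EpiRE, 0.19 in WT, 0.25 in RERE and 0.09 in BRE. The difference lay mainly at ZT16 (SD 0.82 in EpiRE and 0.11 in WT) and ZT0 (0.52 and 0.19), since without both times the SD was 0.23 in EpiRE and 0.21 in WT, and without 1 EpiRE mouse, ZT16 replicate 3, it was 0.30. Epidermal clocks of EpiRE mice may run out of step with each other, in which case Arntl, which peaks opposite to these genes, would deviate against them, and across 24 EpiRE mice it did, with Pearson's r = -0.81 (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 8e-05) and Spearman's rho = -0.81 (permutation p = 2e-05, adjusted p = 0.00016), and r = -0.72 without the 2 mice farthest from the median. In WT the relation was close to the same (r = -0.78, permutation p = 0.00018, adjusted p = 0.00072; rho = -0.80, permutation p = 0.00021, adjusted p = 0.00084; -0.73 without 2 mice), so it is not particular to EpiRE, and in RERE r was -0.40 (permutation p = 0.0617, adjusted p = 0.164; rho = -0.45, permutation p = 0.0494, adjusted p = 0.132; -0.38 without 2 mice) and in BRE -0.12 (permutation p = 0.632, adjusted p = 0.762; rho = -0.13, permutation p = 0.596, adjusted p = 0.795; -0.14 without 2 mice). Uneven removal of the stop cassette between EpiRE mice stays open.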
